A study of Drosophila melanogaster with 34 samples.

How the data were processed

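RiboMeth-seq maps 2′-O-methylation of ribosomal RNA: RNA is broken by alkaline hydrolysis, a methylated ribose protects the bond next to it, and a methylated position therefore shows few read ends against its neighbours. Per the labels' protocols, 150 ng of total RNA was hydrolysed for 16 min at 96 °C, and the end-repaired fragments were made into small-RNA libraries read in single-end mode of 50 bases. The same text, which names only S2R+ cells, stands beside the heads, and how head RNA was extracted is not given in the sources used here. The sources name Trimmomatic 0.39, Bowtie2 and the build dm6, per the submitters' processing notes. The alignment target, filters and score formula are not given in the sources used here.

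Each of the 34 libraries came with 1 table of the same 72 rRNA positions. The authors deposited 3 scores per site, all on scales that end at 1. The level score of the site, called the methylation score here, was used as deposited; it was picked from its column name and range once the tables were at hand. It lay between -0.230 and 1.00, and 2 of 2448 scores were below 0, so it is not a bounded fraction. The other 2 deposited scores entered only as alternatives. The deposited coverage signal gives reads over the position, without normalization. Read ends at the position, 5′ and 3′, were deposited as whole numbers, with a placeholder of 0.1 standing for none in 141 of the 5′ and 13 of the 3′ values. Since neighbouring positions were not analysed here, no score was recomputed, and adjacent sites can share neighbours in their scores. The position numbers are those of the site names in the tables, on the 18S, 28S and 5.8S rRNA; 26 sites carry a different number in a second name, which was not used. Of 109 guide RNA identifiers listed beside the sites, 1 was named by the reference gene table, so sites and not guides are reported by name. A low line character in 10 site names is not explained in the sources.

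Median coverage over the 72 sites ran from 28370.5 to 104242 between libraries, and the coverage of single sites from 119 to 355472. These values cover listed positions only and are not the library's depth. Near a score of 1 few read ends remain, so the relative counting error of the ends is larger there. No interval for a single library was computed because the score's formula was not stated.

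Groups came from the labels. S2R+ cells had 4 LacZ and 4 Fib knockdown libraries. Heads had 3 sucrose controls, 3 paraquat libraries, 4 libraries each at 18, 25 and 29 °C, and 4 each on low-nutrient food (low sugar and, as labelled, no a.a.) and 1x food. Library numbers in the tables fall into separate runs, which were taken as library sets: replicates 1 and 2 of both cell groups in set A, replicates 3 and 4 in set B, the paraquat experiment in set C, and the heat and nutrient experiments in set D. The sources do not say whether replicates were separate cultures or separate pools of flies, so p-values measure only the spread between these libraries, which could be technical. In all 48 within-group pairs of libraries the read ends differed beyond sampling noise (lowest chi-square over its degrees of freedom 1.57, highest p = 0.00569), so no pair looked like 1 library deposited again. Repeat libraries of the same RNA could differ as much, so this does not show separate samples; each library was counted once because the labels number it as a replicate.

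Each site was tested on the linear score with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 72 sites and a threshold of 0.05. Each comparison used its own groups; the 3 temperature groups shared 1 fit, and a second fit took temperature as a number. LacZ cells were set against the mean of the 3 head control groups. The mean score over the 72 sites, 1 value per library, was compared with exact two-sided permutation tests over all regroupings in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3. For cells against heads random regroupings had been planned, and all of them were run instead. Classes of sites (rRNA, base, and a mean score of at least 0.9, from 0.5 to 0.9, or under 0.5) were tested in the same way, alone and against all other sites, with adjustment over the classes of a comparison; classes under 3 sites are values only. The annotation as guide listed, unknown or methyltransferase named was added as a class after the tables were seen.

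These designs, the other settings and the rule for named sites were set before the data were examined. The rule takes, for the knockdown and for cells against heads, the 15 largest falls and 10 largest rises among sites that passed, and the 5 smallest differences of all. For each stress comparison it takes the 10 largest differences per direction, and the 5 smallest p where fewer than 5 passed. Alternatives were a replicate block, the log2 odds of the score with 0.01 added (with scores below 0 set to 0, a step added when such scores were seen), centring on the library median, leaving out sites with a mean under 0.2, trend and robust options, an exact permutation test per site, a minimum difference of 0.1, the other deposited scores, other library choices, and leaving out each library. Library weights, coverage as a covariate and the library set as a random block were added later, as was a test of whether the knockdown differed between library sets.

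Replicate numbers were checked for pairing from the correlation of deviations from the group means. In the knockdown, same-numbered Fib and LacZ libraries correlated at 0.331, 0.238, 0.154 and 0.109 across sites for numbers 1 to 4, which meets the rule for pairing, although the best match of numbers 2, 3 and 4 was another number of the same library set. The fit with the replicate block called 60 sites, 58 of them shared with the 58 called without it.

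The fit was tested on simulated data: 72 sites with the real means and spreads, 24 of them lowered and 48 left as they were, in 100 runs per comparison. For the knockdown, falls of 0.05, 0.1 and 0.2 were called at 41.0%, 68.1% and 89.9% of sites. Falls of 0.02, 0.05 and 0.1 were called at 76.0%, 93.0% and 98.1% for paraquat, 74.2%, 89.8% and 96.1% for 29 against 18 °C, and 69.1%, 94.9% and 99.4% for the nutrient comparison. Between 0.57 and 0.91 of the 48 sites left as they were passed per run. The simulated scores had control means, independent normal noise and the same averaged spread in both groups of a site. Only the groups compared were fitted. The rates therefore do not cover unequal spreads, shifts shared by a library or library set, or the joint fit of the temperature groups.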

Results

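2′-O-methylation of rRNA was measured by RiboMeth-seq at 72 sites of Drosophila melanogaster, 24 in 18S, 47 in 28S and 1 in 5.8S rRNA. The methylated base was A at 28 sites, G at 21, C at 14 and U at 9. The site annotation in the tables lists guide RNAs for 59 sites, names a methyltransferase for 2 and gives the guide as unknown for 11. The 34 libraries came from 2 sources. The first was the cultured Drosophila line S2R+, treated with double-stranded RNA against Fibrillarin (Fib; 4 libraries) or against the bacterial gene lacZ as a control (4 libraries). The second was female fly heads (26 libraries) from experiments on oxidative, heat and nutrient stress. Median coverage per library lay between 28370.5 and 104242 reads over a site. Scores are quoted as mean ± SD between libraries, and a score near 1 stands for strong protection from hydrolysis.

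Fibrillarin is the catalytic methyltransferase of box C/D small nucleolar ribonucleoproteins, in which a guide RNA pairs with the target rRNA. The knockdown asks which sites depend on it. Of the 72 sites, 58 fell, 0 rose and 14 did not pass the test. The largest fall was at 18S Am469, from 0.838 ± 0.0150 to 0.376 ± 0.137 (n = 4 each; adjusted p = 0.000318, limma). 18S Um586, 28S Gm2774, 18S Um1357 and 28S Cm3480 fell next, with changes of -0.461, -0.426, -0.416 and -0.407. The smallest adjusted p of the comparison belonged to 28S Gm2774, 2.45e-05, at scores of 0.947 ± 0.00395 in control and 0.520 ± 0.0531 in knockdown cells. At 28S Gm2774 the coverage was 24377 to 60590 reads per knockdown library.

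The sites that fell most lay in both large rRNAs. In 18S rRNA, Am425, Am441, Cm419, Cm1303, Cm1367 and Gm475 followed, with changes from -0.286 at Cm1367 to -0.378 at Gm475. Am441 began lowest of these, at 0.489 ± 0.0283, and reached 0.195 ± 0.0716. Gm475 varied most among control libraries, at 0.595 ± 0.231, and its adjusted p was 0.0216. It was no longer called without LacZ replicate 1, 2 or 4 (adjusted p = 0.0591, 0.0593 and 0.0520) or Fib replicate 3 or 4 (0.0560 and 0.0590). In 28S rRNA, Am2183, Am3478 and Cm813 fell, with changes of -0.348, -0.297 and -0.256. The single 5.8S site, Gm74, is added here outside the naming rule. It fell by 0.122, from 0.983 ± 0.0129 to 0.861 ± 0.0448. One listed guide, snoRNA:Me18S-G1358c, could be named, and it is listed for both 18S Um1357 and 18S Gm1359, which is also outside the rule and fell by 0.158.

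The falls followed the site annotation. Of the 59 sites with a listed guide, 56 fell, with a median change of -0.169 over all 59. Of the 11 sites of unknown guide, 1 fell (two-sided Fisher's exact test of the 2 classes over sites, p = 7.57e-09, on sites that are not independent). That site was 28S Gm2502, which fell by 0.399, from 0.916 ± 0.00963 to 0.517 ± 0.0845. The 5 least changed sites of all were 18S Am1272, 18S Am[m62A]1976, 28S Am549, 28S Am1897 and 28S Um3162, each annotated as unknown. At 18S Am[m62A]1976, whose name also carries dimethylated adenosine and whose coverage went down to 460 reads, the score was 0.946 ± 0.00604 in control and 0.944 ± 0.0109 in knockdown cells, with a 95% interval of the difference from -0.0219 to 0.0176. Both sites with a named methyltransferase are adjacent and were singled out after their values were seen. 28S Um[Psi]3454, annotated as dependent on CG8939, fell by 0.0511, to 0.857 ± 0.0189. 28S Gm3455, annotated with yeast SPB1, differed by -0.0156 and did not pass (adjusted p = 0.0960). The 3 guided sites that did not pass were 28S Gm3324, 18S Am1806 and 18S Gm1952, also picked after their values were seen. 18S Am1806 missed the threshold of 0.05 at an adjusted p of 0.05001, with a difference of -0.188. The library sets bear on 18S Am1806 and 28S Gm3324, whose control scores were lower in set B (adjusted p = 0.0410 each). A fit with a separate effect per set, with 2 libraries a group in each, was chosen after the results were seen. In it 18S Am1806 fell in both sets, with changes of -0.108 in set A and -0.269 in set B (adjusted p = 0.00145 and 1.26e-05). 28S Gm3324 fell in set B, with a change of -0.349 (adjusted p = 0.00161). 18S Gm1952 had a score of 0.104 ± 0.225 in control cells, but LacZ replicate 3 lay at -0.230 against 0.175 to 0.252 in the others. Without it the control mean was 0.216, and the difference to knockdown cells turned from 0.0865 to -0.0250.

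**Figure D1:**
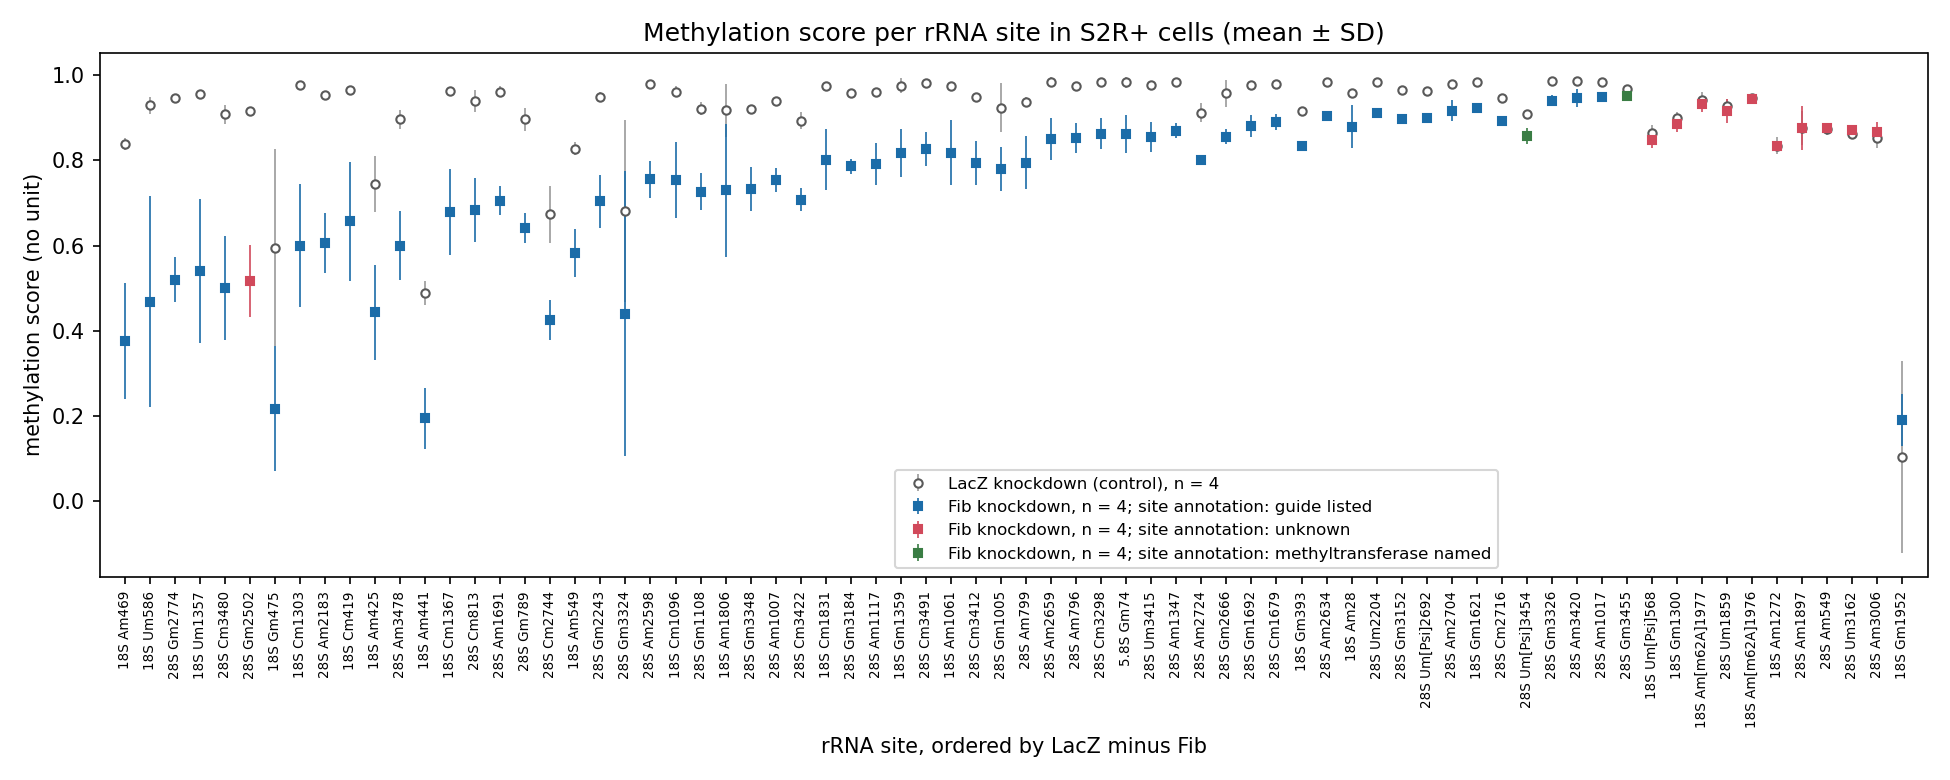
Methylation score (no unit) of each of 72 rRNA sites in S2R+ cells after lacZ (open circles) or Fib knockdown (squares, coloured by site annotation); symbols are means and bars SD of 4 libraries, and sites run from the largest fall, 18S Am469, to the right. Of 11 sites of unknown guide, 10 lie at the right with both means close together, and 28S Gm2502 lies among the largest falls.

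Averaged over the 72 sites, the score was 0.908 ± 0.0109 in LacZ and 0.747 ± 0.0484 in Fib knockdown cells (SD, n = 4 each), a difference of -0.161 (exact two-sided permutation test, p = 0.0286, the smallest this design can give). With the replicate numbers as pairs, the exact p was 0.125, also the smallest possible. Guided sites averaged 0.910 in control and 0.722 in knockdown cells. By base, the mean change was -0.216 at C sites, all 14 of which fell, and -0.134 at U sites. The mean of C sites less that of all others differed by -0.0680 between the groups (exact permutation p = 0.0286, adjusted 0.0857), which did not pass. Across the 72 sites, which are not independent replicates, the change under knockdown and the control level had a Pearson r of 0.00600 and a Spearman rho of 0.128. The r depended on 18S Gm1952: without it, a step chosen after the values were seen, r was 0.255 and rho 0.176. With the level from library set A and the change from set B, which share no library, also looked at later, r was -0.0861 and rho 0.0846, and without 18S Gm1952 0.166 and 0.131.

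The fall was seen within both library sets, and it was deeper in set B. The mean score went from 0.914 to 0.789 in set A and from 0.903 to 0.705 in set B (2 libraries each). A test of the difference between the sets called 40 sites as deeper in set B and 0 as shallower. It rests on the spread between 2 libraries a group in each set, and cannot show how far further sets would differ. Read ends of Fib libraries differed less within a set (chi-square over its degrees of freedom 5.03 and 2.47) than across sets (21.2 to 34.4). In LacZ cells this held in set A (2.71) but not in set B (14.2, across sets 10.2 to 18.4). The plain direction holds for scores as deposited. Centred on the median of each library, which the knockdown itself moved by -0.145, 25 sites were lower and 30 higher.

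**Figure D2:**
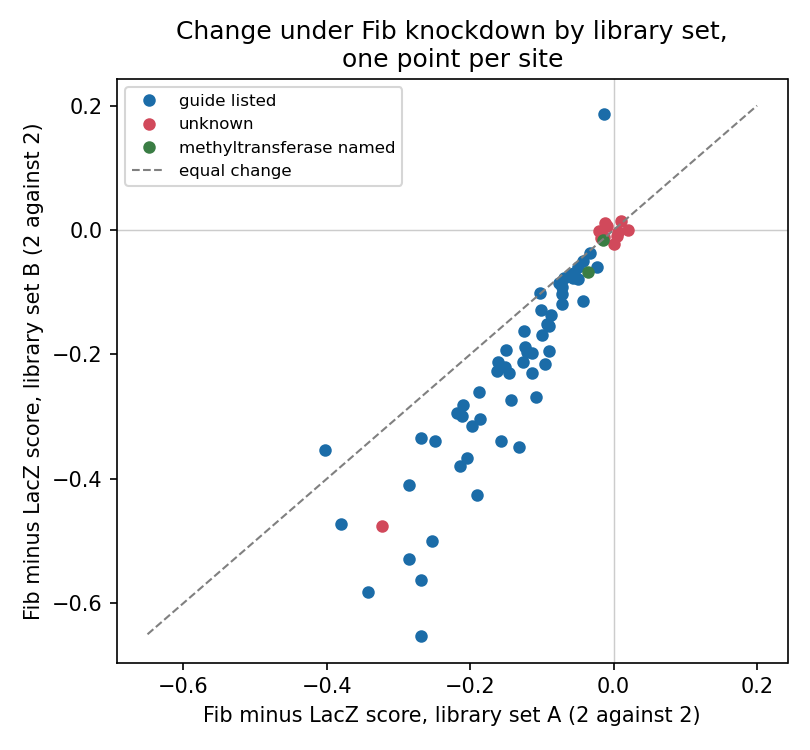
Change of the methylation score under Fib knockdown in library set A (x axis) and set B (y axis), 1 point per site, 2 libraries against 2 in each set, coloured by annotation; the dashed line marks equal change. Of the 58 sites that fell, 56 lie below the line.

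Paraquat is a redox-cycling compound used to cause oxidative stress. Flies were kept for 8 days on 5% sucrose with 2.5 nM paraquat, the unit as labelled, or on sucrose alone. No site passed the test in heads (0 of 72 at the adjusted threshold in limma; 8 at an unadjusted p under 0.05). An exact permutation test per site also gave 0, but with 3 libraries a group it cannot pass whatever the values. The site of the smallest p was 28S Um[Psi]3454, at 0.964 ± 0.00499 in controls and 0.916 ± 0.0141 with paraquat (SD, n = 3 each; adjusted p = 0.0683, limma). It had no 5′ read ends in controls and 0 to 2 with paraquat, at a coverage of at least 34217 reads. The site passed on the log2 odds scale (adjusted p = 0.00635) and in 4 other settings, among them without paraquat replicate 3 (adjusted p = 0.00429); over the settings that could pass its adjusted p ran from 2.90e-06 to 0.496. 18S Am441 differed by 0.0166, 18S Gm475 by 0.0102, 18S Gm393 by -0.0122 and 28S Am3478 by -0.00888, each with an adjusted p of 0.352. The mean score was 0.954 ± 0.00191 and 0.952 ± 0.00118 (SD, n = 3 each; exact permutation p = 0.20, where 3 against 3 cannot go below 0.10). The 95% interval of the difference lay within ±0.05 for 64 of the 72 sites.

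Temperature was compared in heads of flies kept in darkness for 8 days at 18, 25 or 29 °C. Between 29 and 18 °C, 14 sites were higher and 1 was lower at 29 °C. The largest difference was at 28S Cm3422, from 0.905 ± 0.0424 at 18 °C to 0.969 ± 0.00215 at 29 °C (SD, n = 4 each; adjusted p = 0.0225). 28S Gm789 rose by 0.0471 and 18S Cm419 by 0.0347. The smallest adjusted p was that of 28S Gm2243, 2.73e-06, with scores of 0.947 ± 0.00486 at 18 °C, 0.964 ± 0.00401 at 25 °C and 0.986 ± 0.00222 at 29 °C. At 28S Gm2243 the coverage was 88586 to 240905 reads over these 3 groups. 28S Gm2502 rose by 0.0199, 18S Am549 by 0.0223, 28S Cm2744 by 0.0164, 5.8S Gm74 by 0.0144, 28S Cm3480 by 0.0111 and 18S Gm393 by 0.00823. The other 4 rises were smaller. 28S Um3162, annotated as unknown, went the other way, from 0.892 ± 0.0137 to 0.861 ± 0.00409 (adjusted p = 0.0150).

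**Figure D3:**
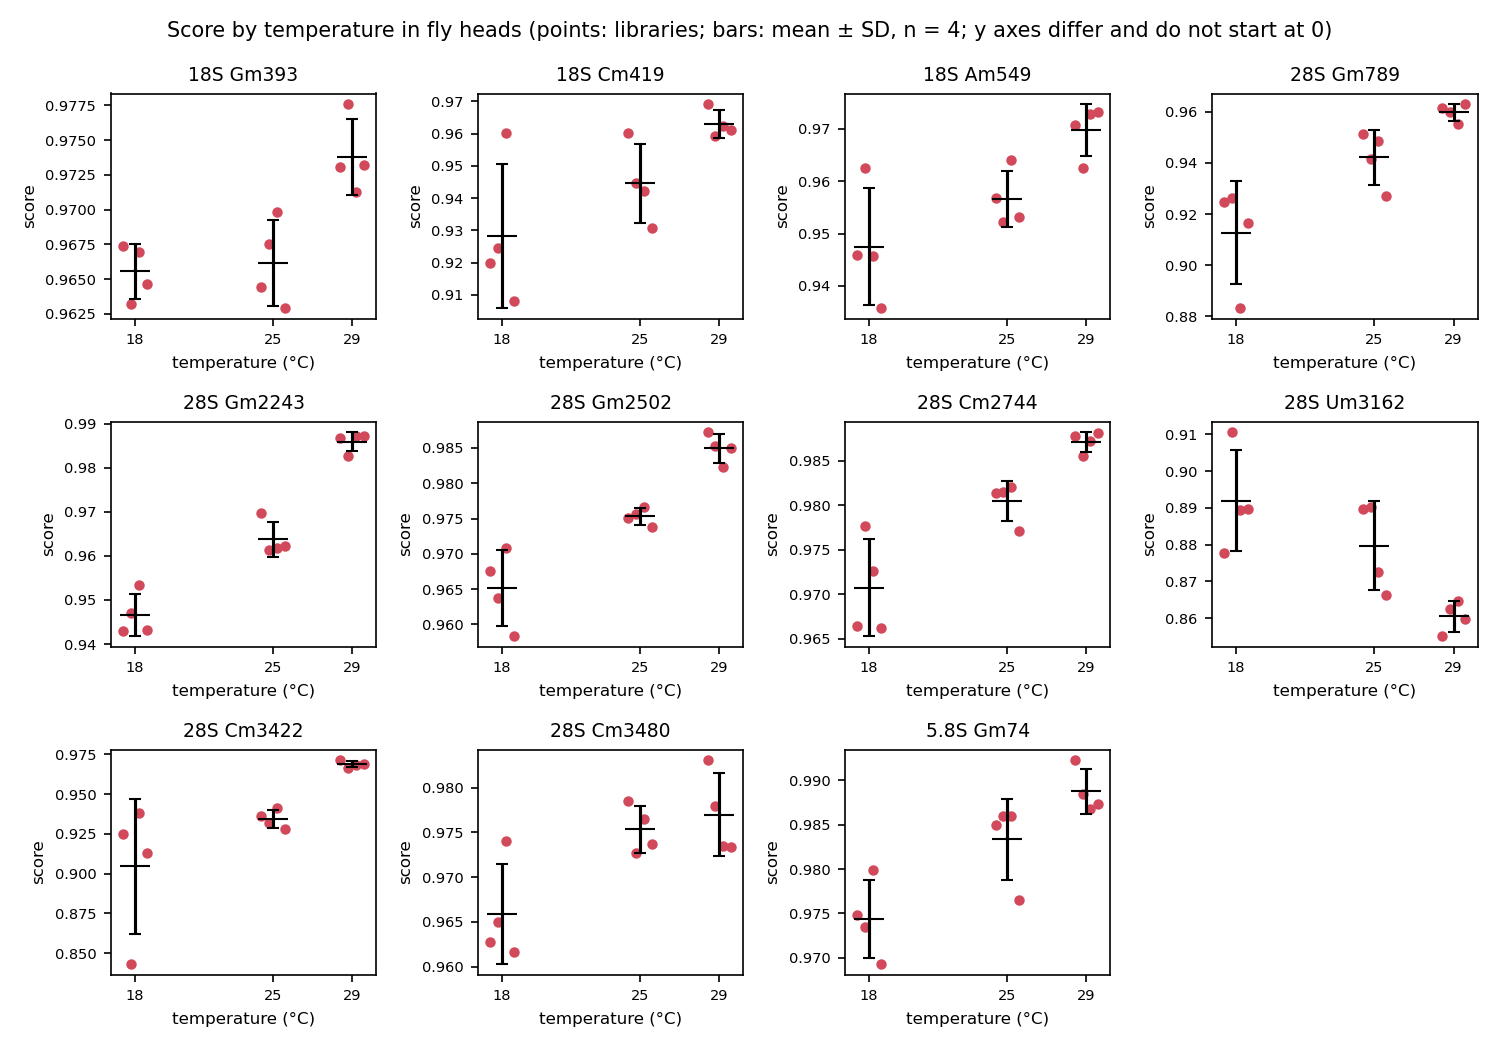
Methylation score (no unit) against temperature (°C) in heads for the 11 sites named in the comparison of 29 with 18 °C; points are libraries, bars mean ± SD of 4 libraries, and the y axes differ and do not start at 0. At 28S Gm2243 the 3 temperatures have means of 0.947, 0.964 and 0.986, and 28S Um3162 is the 1 site with a lower mean at 29 °C.

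Against 25 °C fewer sites passed. At 29 °C 5 sites were higher and 0 lower. 18S Cm1303 rose by 0.0610, from 0.903 ± 0.0165 to 0.964 ± 0.00700 (adjusted p = 0.00369), 18S Am441 by 0.0267, 28S Gm2243 by 0.0222, 28S Gm2502 by 0.00965 and 18S Gm393 by 0.00761. At 18 °C 28S Gm2243 was lower than at 25 °C (difference -0.0172, adjusted p = 0.00565), and it was the single site to pass. On the log2 odds scale its adjusted p was 0.0501. 18S Cm1303 had an 18 °C mean of 0.938, above its 25 °C mean, without passing (adjusted p = 0.0989). The same held for 18S Am441, at 0.946 and 0.931 (adjusted p = 0.314). Neither of these sites passed between 29 and 18 °C (adjusted p = 0.0938 for 18S Cm1303 and 0.222 for 18S Am441). Between 18 and 25 °C, 28S Gm789, 28S Gm2502 and 28S Cm2744 differed by -0.0295, -0.0102 and -0.00971 and did not pass. With temperature as a number, 11 sites rose and 1 fell, the steepest being 28S Cm3422 at 0.00565 per °C (adjusted p = 0.0218), and the 1 that fell was 28S Um3162 at -0.00273 per °C (adjusted p = 0.0171).

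The mean score over sites was 0.941 ± 0.00147 at 18 °C, 0.945 ± 0.00333 at 25 °C and 0.949 ± 0.00138 at 29 °C (SD, n = 4 each). The difference between 29 and 18 °C was 0.00822 (exact permutation p = 0.0286, the smallest possible). The other 2 differences did not pass, at an exact permutation p of 0.0857 each, but 18 against 25 °C did without Heat_25 replicate 4 (-0.00507, exact permutation p = 0.0286) and 29 against 25 °C without Heat_25 replicate 1 (0.00582, exact permutation p = 0.0286). No class by rRNA, base or level passed after adjustment in a temperature comparison, which the design limits. For 29 against 18 °C, 4 of 8 classes (18S, 28S, A and high level) had the lowest possible exact p of 0.0286 (adjusted 0.0571), and at least 5 at that p were needed to pass. The counts depend on the scale and on single libraries. Centred on library medians, 29 against 18 °C gave 21 lower and 9 higher sites, 29 against 25 °C gave 7 lower and 5 higher, and the temperature slope 20 lower and 9 higher. Without Heat_18 replicate 3, 22 sites were higher and 1 lower at 29 than at 18 °C, and 10 were lower at 18 than at 25 °C. For 29 against 18 °C, 7 sites were called without Heat_29 replicate 2, 8 without Heat_18 replicate 2, and 9 without Heat_18 replicate 4 or Heat_29 replicate 1 or 4. For 29 against 25 °C, leaving out any 1 library left 2 to 3 sites, and for 18 against 25 °C 2 sites came without Heat_18 replicate 2 or Heat_25 replicate 1 or 4. 28S Gm2243 kept its call in all of these.

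Nutrition was compared after 10 days on food with 0.25x sugar and, as labelled, no a.a., or on 1x food. In heads, 3 sites were lower on the first, called low-nutrient food here, and 0 higher. 18S Am469 fell by 0.0466, from 0.832 ± 0.00963 to 0.786 ± 0.00721 (SD, n = 4 each; adjusted p = 0.00281). 28S Gm3324 and 28S Gm789 fell as well, with differences of -0.0462 and -0.0153 (adjusted p = 0.02002 and 0.0250). 18S Cm1303 and 18S Um1357 differed by 0.0340 and 0.0178 and did not pass (adjusted p = 0.0638 and 0.0732). Coverage at these 5 sites was at least 15171 reads per library. The mean score was 0.946 ± 0.00739 on the low-nutrient and 0.949 ± 0.00264 on 1x food (SD, n = 4 each, exact permutation p = 0.714). Replicate 4 on low-nutrient food stood lowest, at 0.935 against 0.948 to 0.953, and without it the difference turned from -0.00260 to 0.000921 (exact permutation p = 0.60). On the log2 odds scale 0 sites passed, and with centred scores 2 were lower and 2 higher. Leaving out 1 library gave 1 to 6 sites. The 6, 3 lower and 3 higher, came without Nut_1x replicate 2. 18S Am469 alone was called without Nut_1x replicate 4 or without either of replicates 1 and 2 on low-nutrient food.

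**Figure D4:**
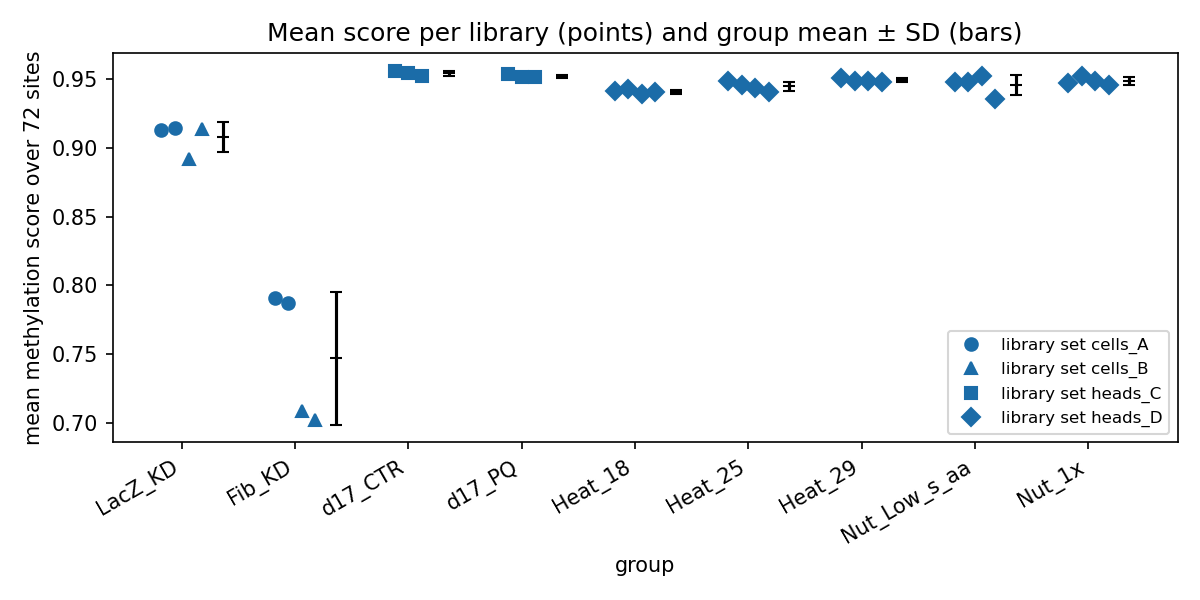
Mean methylation score over 72 sites (y axis, no unit, not starting at 0) for each of 34 libraries, by group (x axis); points are libraries, their shapes library sets, and bars group mean ± SD of 3 or 4 libraries. All 8 cell libraries lie below all 26 head libraries, with the Fib knockdown group lowest at a mean of 0.747.

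Control cells were set against control heads. Of the 72 sites, 49 were lower and 3 higher in LacZ cells than in the mean of the sucrose, 25 °C and 1x food groups (11 libraries). The largest difference was 18S Am441, at 0.489 ± 0.0283 in cells (n = 4) and 0.942 in heads (difference -0.454, 95% interval -0.474 to -0.434, adjusted p = 1.22e-13). 18S Gm475 differed by -0.360, 28S Cm2744 by -0.312, 18S Am425 by -0.162 and 18S Am549 by -0.131, and these 5 were the sites that passed with a difference past 0.1; 28S Gm3324 differed by -0.137 without passing (adjusted p = 0.0686). Next came 28S Am2724, 18S Am1806, 28S Am3478, 28S Gm3348 and 28S Cm3480, at -0.0766 to -0.0673, and 28S Gm2502, 28S Gm1005, 28S Gm789, 28S Cm3422 and 28S Am799, at -0.0617 to -0.0544. Without LacZ replicate 3 the difference at 28S Gm1005 went from -0.0583 to -0.0297 (adjusted p = 4.04e-07). At 18S Gm475 LacZ replicate 3 lay at 0.257 against 0.639 to 0.754 in the others, which widened the difference of -0.360. The 3 sites higher in cells were 18S Cm1303 by 0.0343, 18S Am469 by 0.0240 and 18S Cm419 by 0.0195. The 5 smallest differences were those of 18S Am[m62A]1977, where coverage went down to 142 reads, 18S Am1272, 28S Gm3326, 28S Cm3298 and 5.8S Gm74.

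The mean score was 0.908 ± 0.0109 in the 4 LacZ libraries and 0.949 ± 0.00467 in the 11 head control libraries (exact permutation p = 0.000733, the smallest possible). The mean difference was -0.0569 for 18S and -0.0330 for 28S sites, and 18S sites less all others differed by -0.0245 (exact permutation p = 0.000733, adjusted 0.00147). This rested on 18S Am441 and 18S Gm475: without them, a step chosen after the values were seen, the 18S mean difference was -0.0250, and less all non-18S sites it was 0.00731 (exact permutation p = 0.0960). The median site differed by -0.0197 in 18S and by -0.0205 in 28S rRNA. Across sites, which are not independent replicates, the levels correlated with Pearson r = 0.802 and Spearman rho = 0.706, and without the low site 18S Gm1952 with 0.496 and 0.693. Cells and heads were never in the same library set, so tissue and set cannot be told apart. With the library set as a random block 41 sites passed, and with scores centred on library medians 19 were lower and 36 higher.

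**Figure D5:**
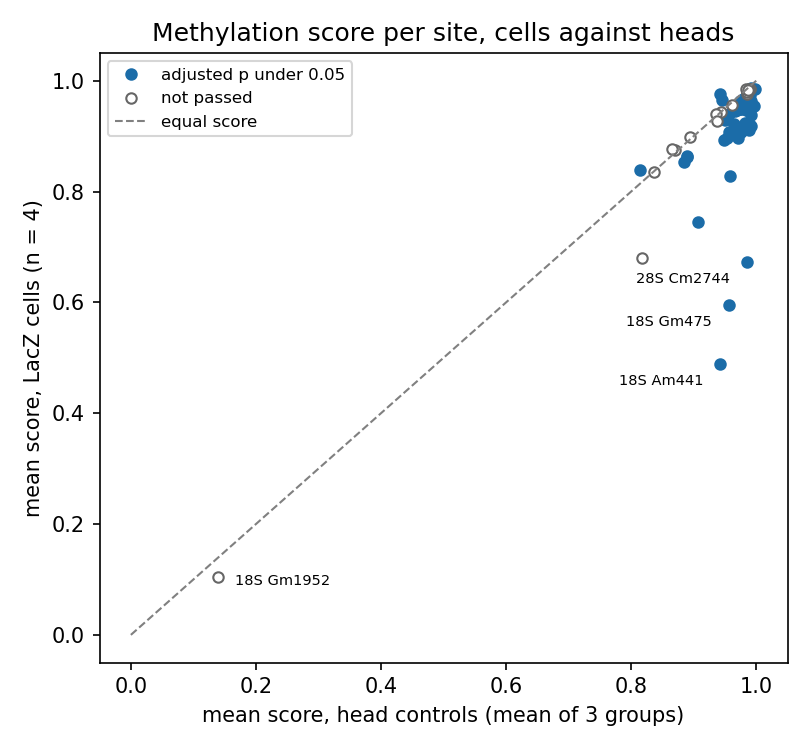
Mean methylation score (no unit) of each of 72 sites in control heads (x axis, mean of 3 groups) and LacZ cells (y axis, 4 libraries); filled points passed the test, open points did not, and the dashed line marks equal scores. 18S Am441, 18S Gm475 and 28S Cm2744 lie farthest below the line, and 18S Gm1952 is low in both sources.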

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

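The tests of explanations and the comparisons with other splits of the libraries in this part were chosen after the results were seen. The comparisons themselves were planned.

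In the knockdown, 40 sites had a deeper fall in library set B than in set A by a test of the difference itself. Over the 58 sites that fell, the mean change was -0.150 in set A and -0.237 in set B, and the falls correlated at 0.896 across sites with a median ratio of 1.57. A shift between the sets of about the same size in every library is argued against. LacZ scores moved by a mean of -0.00596 between the sets (SD over sites 0.0457) and Fib scores by -0.0930. These means cannot decide on a shift that scales with the distance from 1, since LacZ scores lay nearer to 1 than Fib scores. A stronger knockdown in set B may account for a common ratio above 1, but the level of Fib itself is not among the values, so it stays open, as do other differences between the sets in the handling of Fib cells. The real grouping called 58 sites and the highest of the other splits 0, with 1 of 35 as large. The replicate numbers met the rule for pairing, although numbers 2, 3 and 4 matched another number of their library set best. Of the 8 splits that part all 4 such pairs, 1 was as large (60 sites with the replicate block, highest other 0). These are too few for a share under 0.05.

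LacZ_KD replicate 3 and Heat_18 replicate 3 shared low scores at 18S Gm475 (0.257 and 0.819), 28S Gm1005 (0.838 and 0.792) and 18S Gm1952 (-0.230 and -0.207). At 18S Gm475 and 28S Gm1005 the rise of 3′ ends over coverage was a median of 3.14 times that of 5′ ends, where Fib knockdown gave ratios of 0.746 and 0.288. The ratios were 1.80 and 2.60 in LacZ_KD replicate 3, where 5′ ends also rose, 1.56 and 1.60 times. In Heat_18 replicate 3 they were 3.69 and 25.1, with 5′ ends at 1.02 and 0.417 times. This goes with an excess of 3′ ends at these positions, more plainly in Heat_18 replicate 3. For 18S Gm1952 the ratio was 0.874, which argues against that explanation there. A loss of methylation over all guided sites is argued against in Heat_18 replicate 3, where the other 56 sites that fell under knockdown had a median deviation of 0.00704 (quartiles 0.00130 and 0.0124), but stays open in LacZ_KD replicate 3, where it was -0.00746 (quartiles -0.0135 and -0.00119), slightly lower at most sites. What produced the extra 3′ ends also stays open, and no biological explanation was tested, since no group separates these libraries.

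Of the 14 sites higher at 29 than at 18 °C, 9 were still called as higher once scores were centred on library medians. At these 9, which were picked by that call, this argues against an offset of equal size at all sites as the whole cause. It cannot decide on a shift that is larger at lower scores, since centring removes only an equal offset. At the other 5 the median difference became 0.00205 with a median standard error of 0.00216, so an offset may account for them and cannot be told apart from temperature there; for example, 18S Gm393 went from 0.00823 ± 0.00198 (SE) to 0.00253 ± 0.00232. With median coverage as a covariate 13 of the 14 were called, and 13 without Heat_18 replicate 3, which argues against coverage and against that library as their cause. The remaining site in both cases, 28S Gm1108, went from 0.00732 ± 0.00231 (SE) to 0.00650 ± 0.00244 and 0.00654 ± 0.00249, losing its call with a similar difference, and cannot be decided. Temperature as such and a shift that is larger at lower scores remain among the open explanations for the 9 sites.

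Other splits of the libraries bore on the remaining counts. For 29 against 18 °C the real count was 15 and the highest other 0, and for 29 against 25 °C 5 and 0. In both, 1 of 35 splits was as large, the real one. That is the smallest share 35 splits can give, so it argues against chance without excluding it. The temperature slope gave 12 against a highest other of 14, with 2 of 100 splits as large. The nutrient comparison gave 3 against 1, with 1 of 35 splits as large, and cells against heads 52 against 36, with 1 of 100. The shares of splits as large are small for these 3 but do not exclude chance. For the slope another split called more sites, and for the nutrient comparison 1 of 35 is the smallest share possible. In cells against heads the head control groups themselves differed at 32 sites, so their libraries were not interchangeable. For 18 against 25 °C the real count was 1 and 4 of 35 splits gave as many, so chance cannot be excluded. The highest, 14, kept 3 of the 4 libraries of each temperature together. It put Heat_18 replicate 3 with 3 libraries at 25 °C and Heat_25 replicate 4 with 3 at 18 °C. The real comparison without Heat_18 replicate 3 called 10 sites, which points to that library standing apart. Heat_25 replicate 4 moved as well, and its mean score of 0.941 lay within the range at 18 °C. Whether there is another structure was not tested. For paraquat the real count was 0 and the highest other 0, and all 10 splits tie, too few for a share under 0.05.

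Some single values stood far from their group. The mean score of LacZ_KD replicate 3, 0.892, lay below the other 3 of its group (0.913 to 0.915), as did its 28S Gm1005 score, 0.838 (others 0.946 to 0.959), and its 5.8S Gm74 score, 0.964 (others 0.989 to 0.991). 28S Gm2243 was 0.970 in Heat_25 replicate 1 (others 0.961 to 0.962) and 0.983 in Heat_29 replicate 2 (others 0.987). In Heat_25 replicate 4, 28S Cm2744 was 0.977 (others 0.981 to 0.982) and 5.8S Gm74 was 0.977 (others 0.985 to 0.986). 18S Am549 was 0.954 in Nut_1x replicate 1 (others 0.963 to 0.964). Outside the scores, the log2 ratio of 5′ to 3′ read ends in replicate 4 on low-nutrient food was -1.002, against -0.222 to -0.0983 in the other 3. Of 151 groups of values examined, 9 held such a value, where chance alone gives about 1 in 20 (7.55).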

How the results depend on the processing

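Settings by library weights, the coverage covariate and the random library set were chosen after seeing the data. The cause of each change was not tested, except that an exact permutation test per site with 4 libraries a group can pass the adjusted threshold only where most sites reach its lowest p (57 sites in the knockdown, 0 in the heat and nutrient comparisons) and with 3 a group not at all, that no stress difference reached 0.1 (0 sites with that minimum, and 5 in cells against heads), and that 4 pairs, or 2 libraries a group, bound the exact p. The count of 58 sites in the knockdown stayed within 1.5 times in all other settings run (57 to 59 without 1 library; 60 with the replicate block). Apart from the minimum of 0.1, so did that of 52 in cells against heads (49 to 53 without 1 library), though centring on library medians turned the split of directions in both.

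For paraquat, the log2 odds scale, trend and robust options, library weights and a fit of all heads each called 1 site against 0, and leaving out 1 library 0 to 1. For 18 against 25 °C (1 site), the log2 odds scale called 0, trend and robust 6, the A score 3, library weights 10 and all heads 5; leaving out 1 library called 1 to 10. For 29 against 25 °C (5 sites), centring called 12, trend and robust 3, the A score 2, the mean score column 3, library weights 10 and the replicate block 2; leaving out 1 library called 2 to 3. For 29 against 18 °C (15 sites), centring called 30, library weights 24 and leaving out 1 library 7 to 23. The temperature slope (12 sites) called 29 with centring, 21 with library weights and 5 to 21 without 1 library. The nutrient comparison (3 sites) called 0 on the log2 odds scale, 1 with the A score, 5 with library weights and 1 to 6 without 1 library.

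Mean scores over sites kept their direction in all settings run but the nutrient difference, which ran from -0.00483 to 0.000921 without 1 library. The knockdown difference of -0.161 had an exact p of 0.125 with the replicate block, and was -0.125 within set A and -0.197 within set B, where 2 libraries a group cannot pass; without 1 library it was -0.176 to -0.146. For 29 against 18 °C the difference was 0.00570 as a median over sites (exact p = 0.0571) and 0.00822 with the replicate block (exact p = 0.125), and 0.00757 to 0.00885 without 1 library. For 29 against 25 °C it was 0.00454 without low sites (exact p = 0.0286) and 0.00316 to 0.00582 without 1 library. It was -0.00507 to -0.00240 for 18 against 25 °C, -0.00318 to -0.00131 for paraquat and -0.0427 to -0.0351 for cells against heads.

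Of the named sites' values in other settings, 1600 stayed on their side of the threshold, 171 lost a call, 34 gained one and 6 reversed, all on centring: in the knockdown 18S Am1272 to 0.144, 18S Am[m62A]1976 to 0.143 and 28S Am1897 to 0.144, and in cells against heads 18S Am[m62A]1977 to 0.0273, 28S Cm3298 to 0.0249 and 5.8S Gm74 to 0.0246. In the knockdown 9 calls were lost, all at 18S Gm475, which varied among LacZ libraries, but for 28S Am3478 with the A score (-0.0787, adjusted p = 0.460). Site classes kept their side of an unadjusted p of 0.05 in 54 settings, lost it in 8 and gained it in 3. Outside the knockdown, replicate numbers did not pair the libraries: for the heat, nutrient and paraquat comparisons correlations of same-numbered libraries ran below 0 for at least 1 number, and the block is only another setting. At high scores few read ends remain, so their relative counting error is larger. How this bears on differences of the linear score near 1 was not tested.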

Other observations

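The tests between head control groups, the base count at 29 °C and the coverage ratio below were chosen after the values were seen; the prediction on guide number was written before its result.

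The head control groups differed among themselves. By an F test in limma, 32 of the 72 sites differed between flies on sucrose, flies at 25 °C and flies on 1x food. The pairwise counts were 26 for 25 °C against sucrose, 18 for 1x food against sucrose and 4 for 1x food against 25 °C, the last pair being the one from a single library set. After 18S Gm1952, the widest range was at 18S Gm1300, with means of 0.941 on sucrose, 0.855 at 25 °C and 0.886 on 1x food (adjusted p = 0.00769). 18S Cm1303 had means of 0.970, 0.903 and 0.952, and 18S Am425 of 0.865, 0.923 and 0.933. Diet, temperature, light and duration (8 or 10 days) vary between these groups, and the sucrose group is also from another library set. These cannot be told apart.

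The sites higher at 29 than at 18 °C were mostly C and G among all libraries. Of 35 C and G sites 13 were higher, and of 37 A and U sites 1 was (two-sided Fisher's exact test over sites, p = 0.000211, on sites that are not independent). The contrast depended on single libraries. Without Heat_18 replicate 3 it was 16 C and G against 6 A and U sites (Fisher's exact p = 0.01003), and it did not pass without Heat_18 replicate 2 or Heat_29 replicate 1 (6 against 1 in both, exact p = 0.0523) or Heat_29 replicate 2 (5 against 1, exact p = 0.102); 7 to 9 C and G sites stood against 1 without Heat_18 replicate 1 or 4 or Heat_29 replicate 3 or 4. By library, in a test added after this was seen, the mean of C and G sites less that of A and U sites was higher at 29 °C by 0.00928 (exact permutation p = 0.0286, the smallest possible). It did not pass without the 3 sites low in Heat_18 replicate 3, 18S Gm475, 28S Gm1005 and 18S Gm1952 (0.00548, exact permutation p = 0.0571). Nor did it pass without Heat_18 replicate 3 (0.00539, exact p = 0.0857) or without Heat_29 replicate 1, 2, 3 or 4 (exact p = 0.143, 0.114, 0.0571 and 0.0571).

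The number of guide RNA identifiers listed for a site was put forward as a factor in how far it fell under Fib knockdown, with more guides predicted to go with smaller falls. Across 59 guided sites the Spearman rho with the signed change was 0.0516 (permutation p = 0.698; Pearson r = 0.0171), so the prediction was not met. The 23 sites with 1 identifier had a median change of -0.188 and the 23 with at least 3 a median of -0.143. Identifiers need not be expressed guides, and their expression was not analysed here.

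Sites differed in their spread within groups, which in the cell groups also holds differences between the library sets and so is not measurement error alone. At 28S Gm3324, for example, set B less set A was -0.354 in LacZ and -0.571 in Fib cells. The SD within groups, pooled over the 9 groups, had a median of 0.0180 over sites, was under 0.02 at 44 sites and at least 0.05 at 8, and ran from 0.00471 at 28S Gm3455 to 0.139 at 28S Gm3324. Near the 3′ end of 18S rRNA, coverage at Am[m62A]1976 was 1.51% ± 0.234 (SD, n = 4) of that at Gm1952 in LacZ cells and 0.799% ± 0.187 (SD, n = 11) in head controls (exact permutation p = 0.000733), and 1.81% ± 0.370 (SD, n = 4) in Fib knockdown cells (exact permutation p = 0.286 against LacZ).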
